A study of Mus musculus with 12 samples.

How the data were processed

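The series holds 12 mouse libraries, 3 in each of 4 groups given by tissue (dentate gyrus, DG, or subventricular zone, SVZ) and genotype (control or Dpy30 KO). Per the labels' protocols, total RNA was isolated with a Direct-zol kit, polyA+ RNA was selected in repeated rounds and libraries were made with an Agilent mRNA kit and sequenced at a service laboratory. Whether the library kit kept the strand is not given in the sources used here, so reads from a gene and an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, the processing used CASAVA 1.8.4, TopHat2 2.1.0 and Partek with GRCm38 (mm10). These notes give no roles, settings or annotation.

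Of each tissue, the deposited table held FPKM values of 40483 transcripts in 6 columns, named in the file names as scaled by the trimmed mean of M-values (TMM). The columns name a group and not a replicate, so the libraries are called a, b and c in column order. A second set of deposited tables held, per transcript, the authors' own comparison of KO and control: a p-value, a step-up FDR, a signed fold change (control over KO, positive where control was higher) and the mean FPKM of each group, per the file headers. The model behind these p-values is not given there. The comparison tables named genes and transcripts, whereas the FPKM tables gave a gene name only. Rows were joined by gene name and by both group means within a relative difference of 0.0001. All 40483 rows of each tissue joined, 56 in the DG and 64 in the SVZ to more than 1 transcript of the same gene, and 87 rows whose names a spreadsheet had turned into dates joined on their means alone. Transcripts were summed to 17990 genes. The number of per-sample columns left unused was 0. Pooled columns of normalized reads beside the DG comparison were left out, since their order did not follow its transcripts, as were lists of gene names pasted beside enrichment output. TMM scaling takes most genes as unchanged between libraries, and FPKM moves with the abundance of all other RNA in a library. Estimates of single transcripts depend on how reads were shared between isoforms, which summing to genes reduces.

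The tables used here hold FPKM and no read counts, so no count model was fitted. In genes with a single transcript row, low FPKM values times transcript length fell on steps, and the step gave the FPKM that 1 read is worth in a transcript of 1 kb, 0.01516 to 0.03744 by library. Of these low values, 57.5% to 63.5% lay within 0.1 of a whole number of reads, where chance gives 20.0%. This was too few to recover the reads themselves. The inverse of the step, 26.7 to 66.0 reads per FPKM in a transcript of 1 kb, measures the depth of a library. A gene at 0.5 FPKM over 1 kb therefore rests on few reads, and low values are less reliable than high ones.

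Genes with a mean of at least 0.5 FPKM over the 6 libraries of a tissue were tested, 15454 in the DG and 15159 in the SVZ. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), KO minus control within each tissue's table, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and folds in the text are ratios of mean FPKM. The difference of the KO effects between tissues was tested in a model of the 4 groups over 14922 genes. Levels were not tested across the 2 tables, which were normalized separately. Lists of genes were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists with at least 5 measured members. Dpy30 was also tested by exact permutation. In tests of explanations, the spread of a list median was the larger of a bootstrap SE over its genes and the SE over libraries of the list's mean value, a choice made after the values were seen.

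Before the data were examined, 33 lists were fixed: subunits of the SET1/MLL complexes, neural stem cells and radial glia, cell cycle and DNA replication, intermediate progenitors, immature neurons and neuroblasts, dentate granule neurons, mature neurons and synapses, GABAergic and striatal neurons, hippocampal CA pyramidal neurons, thalamic and habenular neurons, astrocytes, oligodendrocyte precursors, myelinating oligodendrocytes, ependymal cells and motile cilia, choroid plexus, microglia and macrophages, endothelial cells and pericytes, meningeal and vascular fibroblasts, blood, reactive gliosis, interferon response, p53 targets and senescence, Hedgehog, Wnt and Notch signalling, HOX and developmental patterning, cholesterol biosynthesis, oxidative phosphorylation, ribosomal proteins, mitochondrial genome, immediate early genes, heat shock and stress, and a sex check. The last was not tested as a set, 0 genes of the mitochondrial list were in the tables, and 2 of the HOX list were measured, so that 30 lists were tested. Symbols that did not match were looked up among the synonyms of RefSeq protein-coding genes.

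The genes named were also set by a rule fixed before the data were examined: Dpy30; per tissue the 10 higher and 10 lower with the largest change among genes past the threshold with groups that do not overlap, remaining places going to the smallest p and said not to pass, with gene models without a symbol skipped; the 4 members of each list with the smallest p; up to 5 in each direction that pass in both tissues; and the 5 in each direction with the smallest p of the difference between tissues. SVZ values of genes named for another part of the rule, and all values without the library labelled KO a, were chosen after the values were seen. Some genes that this rule names are not reported here. That library, a leave-one-out setting planned for every library, was picked out because its Dpy30 went against its label.

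Alternatives planned beforehand were a pseudocount of 0.1, no filter on low values, a mean of at least 2 FPKM, quantile normalization, median centring of the libraries, leaving out each library, robust eBayes, single transcript rows, an unadjusted p under 0.05 with a fold of at least 2, the authors' table at an FDR under 0.05 and camera with an estimated correlation. Added later were a term for the sex of the mouse (male where Kdm5d was above 0.5 FPKM), a term for the mean of the striatal list in the DG, and camera on the difference between tissues. The fits were tested on simulated data made from the real means and residual spread with 200 genes changed. For the DG, 53.7%, 88.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold on the log2(FPKM + 1) scale were called, with 8 false calls among 15454 genes. For the SVZ these shares were 38.8%, 95.5% and 100%, with 5 false calls among 15159 genes. For the difference between tissues they were 26.2%, 84.6% and 100%, with 15 false calls among 14922 genes. Camera with the preset correlation called 0 of 30 lists in either tissue on simulated data without changes and without correlation between genes. The power of camera with an estimated correlation was not measured, so a missing call there is no evidence that a list was unchanged. On the real values with the preset correlation, splits that mixed the genotypes gave up to 18 DG and 13 SVZ lists. Within groups no pair of libraries held near-identical values: the SD of the log2 difference over genes was 0.20 at the least, between SVZ KO b and KO c. Gene positions are from GENCODE vM21 on GRCm38. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.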

Results

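RNA was sequenced from mouse brain tissue of the dentate gyrus (DG), the hippocampal region in which neurons are generated after birth, and of the subventricular zone (SVZ), the neurogenic region along the lateral ventricles. The samples hold neural stem and progenitor cells together with the cells around them. Control mice carried the genotype hGFAP/+;Dpy30F/+ and knockout (KO) mice hGFAP/+;Dpy30F/-. Each of the 4 groups (DG control, DG KO, SVZ control, SVZ KO) held 3 libraries, named a, b and c here in the order of their table columns, a name that pairs nothing across groups. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be technical in part. Values are FPKM (fragments per kilobase of transcript, scaled to the size of the library) with the TMM scaling of the authors' tables, summed per gene. Steps in the low values of genes with a single transcript row gave the depth behind each library as the reads that 1 FPKM stands for in a transcript of 1 kb. It was 26.7 to 42.2 reads in the DG control libraries, 48.5 to 66.0 reads in the DG KO libraries, 37.0 to 46.0 reads in the SVZ control libraries and 34.1 to 50.2 reads in the SVZ KO libraries, so that the DG KO libraries were all deeper than the DG controls. Xist and the Y-linked Kdm5d marked DG control c, DG KO a and SVZ control a as female and the other libraries as male.

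The first question was whether the deleted gene was lower in the KO libraries. Dpy30 (ENSMUSG00000024067.13) encodes a core subunit of the SET1/MLL histone H3 lysine methyltransferase complexes. It lies on chromosome 17 of GRCm38, from 74299474 to 74323944 on the minus strand. In the DG, Dpy30 was at 8.43, 8.38 and 10.1 FPKM in the control libraries and at 6.22, 6.89 and 5.68 FPKM in the KO libraries, means of 8.98 ± 0.991 and 6.26 ± 0.605 FPKM (SD, n = 3). Every DG KO library lay below every DG control library, and the log2 fold change was -0.46 (SE 0.11) with a limma adjusted p of 0.073. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. In the SVZ, Dpy30 was at 7.73, 8.25 and 9.43 FPKM in the controls, at 5.04 and 4.87 FPKM in KO b and KO c, and at 8.83 FPKM in the library labelled KO a. With all 6 SVZ libraries the log2 fold change was -0.42 (SE 0.20, limma adjusted p = 0.42) and the exact two-sided permutation p was 0.3. Without the library labelled KO a the log2 fold change was -0.67 (SE 0.12) and the limma adjusted p 0.023, a setting planned for every library and singled out here, after the values were seen, because Dpy30 goes against this label. The counts of SVZ genes and the SVZ lists that were called are therefore given with all libraries and without that library. Transcripts from cells outside the deletion and reads outside the deleted part both add to these values, and the exons deleted are not given in the sources used here. If the KO genotype (Dpy30F/-) lacks an allele in all cells, Dpy30 could be lower in KO without the conditional deletion. A lower value therefore does not by itself show that this deletion took place.

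**Figure D1:**
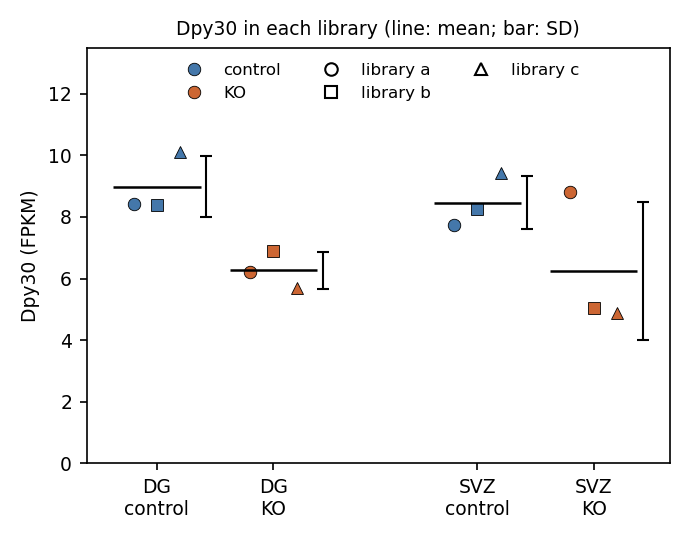
Dpy30 in FPKM (vertical axis, from 0) in each of the 12 libraries, grouped by tissue and genotype on the horizontal axis; symbols mark the library, lines the group mean and bars the SD of 3 libraries. The DG KO libraries lie between 5.68 and 6.89 FPKM, below all DG controls, and the SVZ library labelled KO a lies at 8.83 FPKM, among the SVZ controls.

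The DG comparison asked which genes differ between KO and control dentate gyrus. Grin2c (ENSMUSG00000020734.13), an NMDA receptor subunit, fell from 7.01 ± 1.29 to 0.364 ± 0.083 FPKM (SD, n = 3), a log2 fold change of -2.54 (SE 0.14, limma adjusted p = 0.0089). Gpr17 (ENSMUSG00000052229.5), a receptor of oligodendrocytes on their way to maturity, fell from 37.6 ± 7.73 to 8.95 ± 1.05 FPKM. The metabotropic glutamate receptor gene Grm2 fell from 10.8 ± 2.31 to 2.12 ± 0.077 FPKM, and Aldoc, the aldolase of astrocytes, from 186 ± 20.4 to 75.3 ± 6.44 FPKM (limma adjusted p = 0.028 for each of the 3). Lynx1, a modulator of nicotinic receptors, fell 3.16-fold, the axonal Caspr gene Cntnap1 2.69-fold, the BMP antagonist gene Chrd 3.49-fold, the vesicle release gene Cadps2 2.30-fold and Nrip3 2.94-fold. Erdr1 also fell, 2.35-fold, but its reads can be shared with near-identical sequence on the sex chromosomes, so its value is uncertain. Among genes that rose, Sox3 (ENSMUSG00000045179.9), a transcription factor of neural progenitors on the X chromosome, went from 2.71 ± 0.480 to 8.23 ± 1.51 FPKM (log2 fold change 1.31, SE 0.16, limma adjusted p = 0.041). Pipox, a peroxisomal oxidase, rose 5.36-fold from 0.655 FPKM and the incretin receptor gene Gipr 4.01-fold from 0.679 FPKM. Col16a1 rose 2.82-fold, Txnrd3 2.29-fold, Rdh5 2.15-fold, Ethe1 2.02-fold and the ribosomal protein gene Rpl23 2.15-fold. The kinetochore genes Cenpx and Apitd1 rose 1.97-fold and 3.47-fold, Apitd1 from 0.616 FPKM. All 20 of these genes were separated between the groups in all 6 libraries, as the rule that chose them required.

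In all, 108 of 15454 genes passed in the DG, 52 higher and 56 lower in KO, by limma-trend on log2(FPKM + 1) with Benjamini-Hochberg adjustment. The split was 43 higher and 86 lower after quantile normalization, and 32 higher and 99 lower after median centring. The groups did not overlap for 33.7% of the tested genes, where chance gives 10%. The count rests on having all 6 libraries: it was 2, 3 and 2 without control a, b and c, and 0 without KO a, KO b or KO c in turn, while 4092 genes had an unadjusted p under 0.05 with all libraries. It was 3 with the sex of the mouse as a term, an alternative added after seeing the data.

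**Figure D2:**
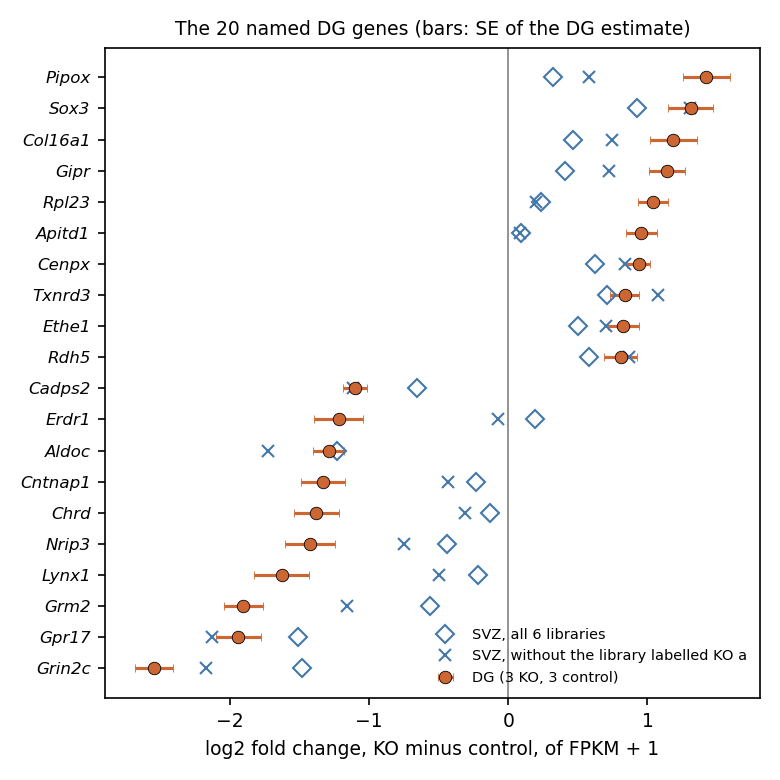
Log2 fold change of FPKM + 1, KO minus control (horizontal axis), of the 20 genes named by rule in the DG (vertical axis). Filled points are the DG estimates with their SE (3 against 3 libraries), diamonds the SVZ estimates with all 6 libraries and crosses the SVZ estimates without the library labelled KO a; Grin2c has the lowest DG value, -2.54, and Pipox the highest, 1.42.

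The list of mature neuron and synapse genes had a negative median log2 fold change in the DG KO, with few members past the threshold. Of the 22 measured members, Eno2 (neuron-specific enolase, from 179 ± 3.81 to 95.2 ± 3.65 FPKM, SD, n = 3) and Grin1 (the obligatory NMDA receptor subunit, 103 ± 5.71 to 65.5 ± 5.66 FPKM) fell past the threshold (limma adjusted p = 0.028 and 0.048). A total of 20 members did not pass, among them the neurofilament gene Nefl with a log2 fold change of -1.03 (SE 0.18, limma adjusted p = 0.055). The log2 fold change was negative for 20 of 22 members and the list median was -0.57. Adjusted over the list alone, 15 fell. The list was called by camera with the preset correlation (adjusted p = 8.84e-14) and not with an estimated one (adjusted p = 0.28 with an estimated correlation). Markers of dentate granule neurons (median -0.36, camera adjusted p = 0.0041) and of hippocampal CA pyramidal neurons (median -0.64, camera adjusted p = 0.0058) were also called lower, with 0 of 18 and 0 of 10 members past the threshold (both adjusted p = 0.79 with an estimated correlation). Without DG control c both medians were -0.23 (camera adjusted p = 0.021 and 0.027). Values of Nptx1, a secreted synaptic pentraxin, were 30.6 ± 10.6 FPKM in control and 11.4 ± 6.43 FPKM in KO, and those of the granule neuron gene Calb1 gave a log2 fold change of -0.73 (limma adjusted p = 0.13). Immediate early genes had a median of -0.41 with 0 of 16 members passing (camera adjusted p = 6.72e-04, and adjusted p = 0.79 with an estimated correlation). Without DG control b that median was -0.16 and the adjusted p 0.055, and it was -0.66 and -0.26 without DG KO a and KO c.

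The lists of ribosomal protein genes and of cell cycle genes had positive median log2 fold changes in the DG KO, with few or no members past the threshold. All 23 measured ribosomal protein genes had positive log2 fold changes, with a median of 0.60. Rpl18 (26.7 ± 1.01 to 43.8 ± 1.82 FPKM, SD, n = 3) and Rpl7 (38.8 ± 1.74 to 65.0 ± 6.59 FPKM) rose past the threshold (limma adjusted p = 0.034 and 0.042), and 21 did not pass, such as Rplp0 with a log2 fold change of 0.68 (SE 0.10, limma adjusted p = 0.052). Adjusted over the list alone, 21 rose. The camera adjusted p was 1.03e-08, and the list was not called otherwise (adjusted p = 0.79 with an estimated correlation). Ribosomal protein genes have many processed copies in the genome, so their values are uncertain where reads are shared with those. All 27 measured cell cycle and DNA replication genes had positive log2 fold changes, with a median of 0.33, and 0 of the 27 passed (camera adjusted p = 0.0023, and adjusted p = 0.82 with an estimated correlation). Without DG KO a that median was 0.52. Birc5, the mitotic survivin gene, was at 1.15 ± 0.274 FPKM in control and 2.73 ± 0.965 FPKM in KO, and the replicative helicase gene Mcm2 at 1.88 ± 0.297 and 3.29 ± 0.847 FPKM. The progenitor gene Fabp7 was at 193 ± 44.1 and 579 ± 185 FPKM, with a limma adjusted p of 0.056. The list of neural stem cell and radial glia genes that holds it had a median of 0.10 and was not called (camera adjusted p = 0.86). The log2 fold change was positive for 14 of 14 markers of meningeal and vascular fibroblasts, with a median of 0.79 (camera adjusted p = 0.0057, and adjusted p = 0.82 with an estimated correlation). Without DG control b the fibroblast median was 0.53 and its adjusted p 0.086. Mgp of this list was at 7.37 ± 3.31 FPKM in control and 18.1 ± 3.32 FPKM in KO. The blood list, led by the alpha globin gene Hba-a1 (97.1 ± 23.1 and 211 ± 24.6 FPKM), had a median of 1.13 and was not called (camera adjusted p = 0.084).

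The list of genes of myelin-forming oligodendrocytes had a median of -1.35 in the DG, with 18 of 19 members negative. The list was called by camera (adjusted p = 1.03e-08), and was not called otherwise (adjusted p = 0.79 with an estimated correlation). None of the 19 members passed by limma, over all genes or adjusted over the list alone. Mbp, the myelin basic protein gene, was at 135, 1435 and 431 FPKM in DG control a, b and c and at 64.2, 59.4 and 62.1 FPKM in the KO libraries, a log2 fold change of -2.80 (SE 0.77, limma adjusted p = 0.090). Mobp gave -3.66 (SE 0.93, limma adjusted p = 0.082). Without DG control b the median of the list was -0.78. That library also had the highest mean log2 value of striatal and GABAergic markers, 5.54 against 3.59 and 3.31 in control a and c and 3.42, 4.55 and 5.24 in KO a, b and c. In the oligodendrocyte precursor list, Gpr17 and the complement-like gene C1ql1 fell (limma adjusted p = 0.028 and 0.0499), while the proteoglycan gene Vcan had a log2 fold change of 1.03 (SE 0.20, limma adjusted p = 0.061). Its median was -0.08, and its call (camera adjusted p = 0.047, and adjusted p = 0.82 with an estimated correlation) was lost after median centring (adjusted p = 0.12), quantile normalization and a minimum of 2 FPKM, with the sex term, and without DG control b (adjusted p = 0.18), DG KO a (0.31) or DG KO b (0.063). The precursor median was -0.19, -0.00202 and -0.16 without DG control a, b and c, and -0.02 and -0.17 without KO a and KO c. Of 19 astrocyte genes, Aldoc passed, and Gfap, the intermediate filament of astrocytes, had values of 69.8 ± 28.0 and 27.2 ± 2.90 FPKM (limma adjusted p = 0.064). Adjusted over the list alone, 5 astrocyte genes fell and 1 rose, and the list median was -0.18 (camera adjusted p = 6.55e-04, and adjusted p = 0.79 with an estimated correlation).

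**Figure D3:**
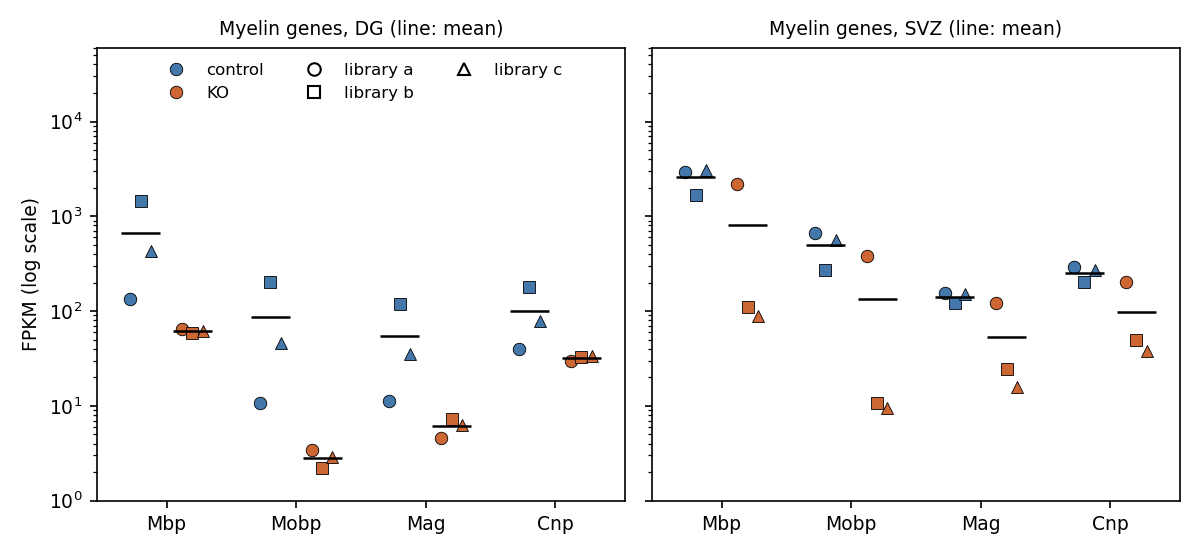
FPKM on a log scale (vertical axis) of 4 myelin genes (horizontal axis) in the DG (left) and SVZ (right) libraries; colours mark the genotype, symbols the library and lines the mean of 3 libraries. Mbp lies at 59.4 to 64.2 FPKM in the DG KO libraries, and at 2211 FPKM in the SVZ library labelled KO a against 112 and 89.6 FPKM in KO b and KO c.

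The SVZ comparison asked the same question of the subventricular zone. With all 6 libraries, 1 of 15159 genes passed by limma, and 1914 had an unadjusted p under 0.05. The gene was n-R5s141 (ENSMUSG00000095749.1), an annotated copy of the 5S ribosomal RNA on chromosome 8, from 123608320 to 123608438 on the minus strand. It was at 0.361 ± 0.141 FPKM in the controls and at 8.33, 8.61 and 12.8 FPKM in KO a, b and c (log2 fold change 2.99, SE 0.18, limma adjusted p = 0.0016). It is 1 of many near-identical copies and polyA selection removes most 5S RNA, so this value is uncertain. It did not pass without SVZ control a (limma adjusted p = 0.060). The further 5S copies n-R5s149 (2.32 ± 1.67 and 11.8 ± 3.49 FPKM) and n-R5s111 (1.07 ± 1.12 and 7.05 ± 2.60 FPKM) did not pass (limma adjusted p = 0.37 for both), and passed without the library labelled KO a (limma adjusted p = 0.035 and 0.044). The metallothionein gene Mt2 was at 65.6 ± 0.581 FPKM in control and 27.1 ± 9.14 FPKM in KO, the striatal neuropeptide gene Tac1 at 37.0 ± 3.90 and 22.4 ± 1.66 FPKM, and Idh1 at 30.9 ± 1.03 and 19.8 ± 1.98 FPKM. The astrocyte connexin gene Gjb6 was at 37.2 ± 5.57 and 19.5 ± 3.33 FPKM, the microglial gene Siglech at 5.42 ± 0.646 and 2.69 ± 0.443 FPKM and the glycosylation gene Man1a2 at 15.5 ± 1.87 and 8.53 ± 0.171 FPKM. The neuronal transcription factor gene Neurod2, at 14.2 ± 1.47 and 27.6 ± 6.45 FPKM, had the opposite sign. None of these 7 genes passed (limma adjusted p = 0.37 for each).

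Glial and vascular gene lists had negative medians in the SVZ with all libraries. Camera called 11 lists, all lower, and none of them with an estimated correlation, where the lowest adjusted p was 0.43. Myelin genes had a median of -1.87 with 20 of 20 members negative (camera adjusted p = 5.85e-14, and adjusted p = 0.50 with an estimated correlation). None of the 20 passed over all genes, and 20 of 20 did when adjusted over the list alone, with the aspartoacylase gene Aspa at 7.11 ± 4.01 and 1.83 ± 1.66 FPKM. Microglia and macrophage genes had a median of -0.46, and astrocyte genes one of -0.51. Neural stem cell and radial glia genes had a median of -0.35. Among them the stem cell surface gene Prom1 was at 5.21 ± 1.24 and 1.76 ± 0.969 FPKM, the neurogenic transcription factor gene Pax6 at 3.08 ± 0.268 and 1.46 ± 0.319 FPKM and Thbs4 at 2.41 ± 0.844 and 0.674 ± 0.322 FPKM. Adjusted over each list alone, 12 of 21 microglial, 11 of 19 astrocyte and 9 of 23 stem cell genes were lower (adjusted p = 0.43 with an estimated correlation for each of these 3 lists). The other lists called lower were endothelial cells and pericytes (median -0.29), immature neurons and neuroblasts (-0.26), meningeal and vascular fibroblasts (-0.41), GABAergic and striatal neurons (-0.34), cholesterol biosynthesis (-0.22), oligodendrocyte precursors (-0.17) and Wnt signalling (-0.07). With estimated correlations their adjusted p ran from 0.43 to 0.59. The neuroblast call was lost without SVZ control b (adjusted p = 0.087), the precursor call without SVZ control b (0.11), control c (0.12), KO a (0.090) or KO c (0.097), and the Wnt call without SVZ control b (0.070), control c (0.29) or KO c (0.096). Without SVZ control a the neuroblast and Wnt medians were -0.42 and -0.12, without control b the neuroblast and endothelial medians -0.10 and -0.16, without control c the precursor and Wnt medians -0.10 and -0.11, and without KO c the cholesterol median -0.15.

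Without the library labelled KO a, 1317 SVZ genes passed by limma, 638 higher and 679 lower in KO b and KO c than in the 3 controls. Leaving out any other SVZ library gave 0 to 2. All 20 myelin genes fell, with a median of -2.75 (camera adjusted p = 5.91e-25, and adjusted p = 0.59 with an estimated correlation). Mbp went from 2569 ± 776 FPKM (SD, n = 3) to a mean of 101 FPKM, Mobp fell 49.9-fold and Mag, the myelin-associated glycoprotein gene, 7.08-fold. Of 19 astrocyte genes 8 fell, among them the glutamate transporter gene Slc1a3 (1.99-fold), and of 21 microglial genes 8 fell and 1 rose, with the purinergic receptor gene P2ry12 down 2.35-fold. Of 23 stem cell and radial glia genes 7 fell, with Prom1 down 4.33-fold and Pax6 2.26-fold. Of 18 cholesterol synthesis genes 5 fell, among them Cyp51 (2.14-fold) and Lss (1.60-fold). Of 24 neuroblast genes 3 fell, among them Cd24a (3.34-fold), and of 18 striatal and GABAergic genes 7 fell and 2 rose, with the dopamine receptor genes Drd1 and Drd2 down 1.88-fold and 1.71-fold. In these astrocyte, microglial, stem cell, cholesterol and striatal lists the adjusted p was 0.59 with an estimated correlation, and in the neuroblast list 0.71. Of 23 cell cycle genes 2 rose, with a list median of 0.17 (camera adjusted p = 0.044, and adjusted p = 0.64 with an estimated correlation). Camera called 13 lists in this setting, none of them with an estimated correlation. Even the myelin list, with 20 of 20 members past the threshold, had an unadjusted camera p of 0.065 with an estimated correlation. Beyond those above, they were immediate early genes (6 of 16 fell and 1 rose, median -0.52), endothelial cells and pericytes (2 of 16 fell), fibroblasts (1 of 11 rose, median -0.50), thalamic and habenular neurons (3 of 12 fell) and Wnt signalling (3 of 16 fell), with adjusted p from 0.59 to 0.64 with an estimated correlation. Of 16 oligodendrocyte precursor genes, Gpr17 fell 4.84-fold and 1 rose, and this list was not called (median -0.16, camera adjusted p = 0.090).

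**Figure D4:**
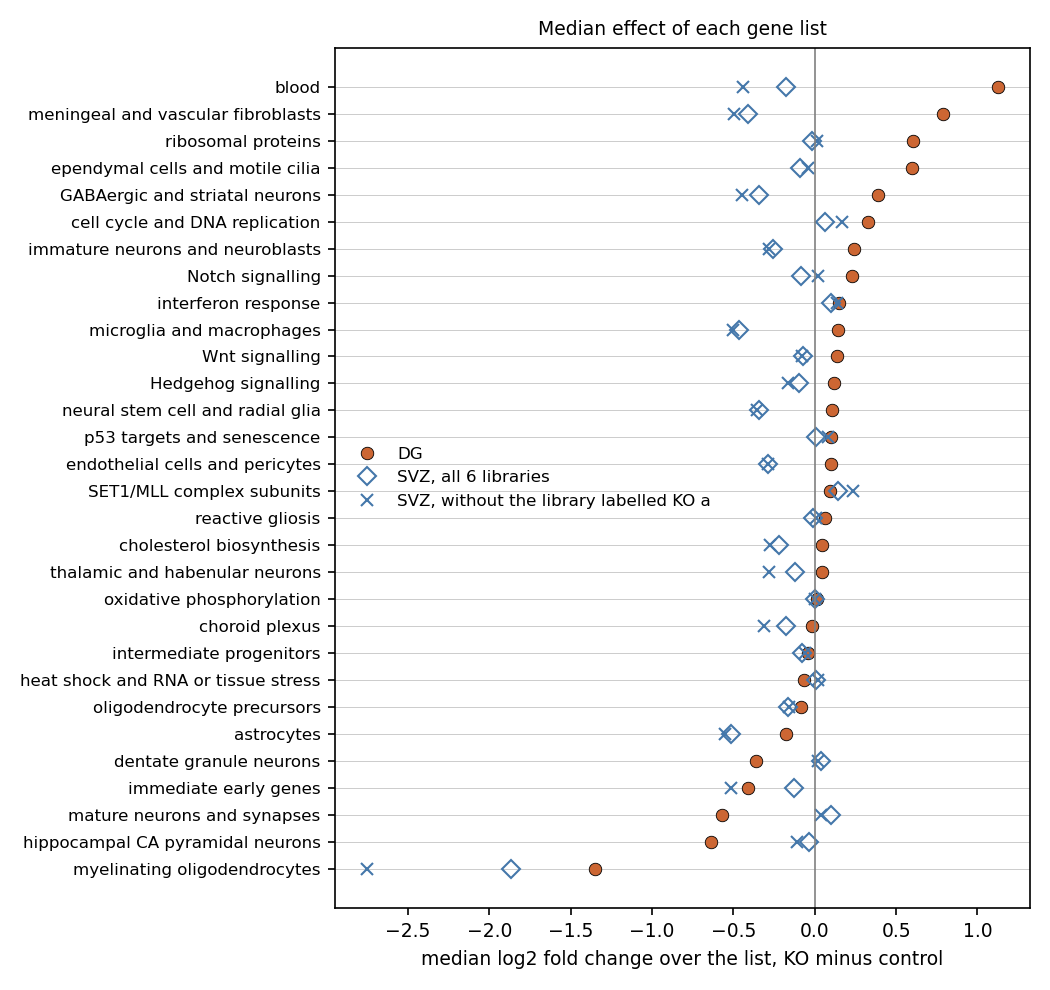
Median log2 fold change, KO minus control (horizontal axis), of each gene list with at least 5 measured members (vertical axis). Circles are the DG, diamonds the SVZ with all 6 libraries and crosses the SVZ without the library labelled KO a; the myelin list is lowest in each, at -1.35, -1.87 and -2.75.

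The overlap of the tissues was examined next. With all libraries 0 genes passed in both tissues, since the single SVZ gene was not among the DG genes. At an unadjusted p under 0.05 there were 4092 genes in the DG and 1914 in the SVZ. Of the DG genes that were also tested in the SVZ, 40 of the 49 higher and 43 of the 55 lower had the same sign in the SVZ, where 55.5% of all genes had a positive value and 44.5% a negative one. Without the library labelled KO a, 33 genes passed in both tissues in the same direction. A total of 12 were higher, where independent lists of these lengths would share 1.97 (Fisher's exact one-sided p = 3.84e-07), and 21 were lower, where independent lists would share 2.43 (Fisher's exact one-sided p = 5.27e-15). Fisher's test takes genes as independent, whereas related genes moved together. The estimated correlation in the SVZ in this setting was 0.83 for the myelin and 0.44 for the astrocyte list. The setting was also singled out after the values were seen, so both p-values overstate the evidence. Grin2c, Gpr17, Aldoc, Grm2 and Cadps2 were the 5 genes lower in both tissues with the largest smaller change, by SVZ log2 fold changes of -2.17, -2.13, -1.72, -1.16 and -1.11 without that library. Among those higher in both, Sox3 had 1.30 (SE 0.22, limma adjusted p = 0.020) and Txnrd3 1.07 (SE 0.12, limma adjusted p = 0.0063). With all SVZ libraries, none of these 7 genes passed in the SVZ (limma adjusted p from 0.37 to 0.60). In the authors' deposited table, tested per transcript, 13 of 40483 transcripts had an FDR under 0.05 in the DG and 1 in the SVZ, the latter n-R5s141. At an unadjusted p under 0.05 with a fold of at least 2, the authors' deposited table held 898 transcripts lower and 1116 higher in KO in the DG, and 782 lower and 749 higher in the SVZ.

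Whether the KO effect differed between the tissues was tested on the difference of the 2 effects, since each tissue has its own table. Of 14922 genes, 5 passed by limma. Among them, Eno2 (ENSMUSG00000004267.16, chromosome 6, 124760053 to 124769673, minus strand) fell in the DG by 0.91 on the log2 scale and had 0.11 in the SVZ, a difference of 1.01 (SE 0.13, limma adjusted p = 0.028). Dagla, a synthase of the endocannabinoid 2-arachidonoylglycerol, had a negative DG value (-0.68) and a positive SVZ value (0.43). The transporter gene Abca9 had 0.45 in the DG and -0.40 in the SVZ, and n-R5s141 had -0.26 and 2.99 (limma adjusted p = 0.040 to 0.046 for these 3 differences). For Mbp the difference was not called (limma adjusted p = 0.94), nor for Dpy30 (limma adjusted p = 0.97). The count of 5 became 64 without the library labelled KO a, 258 without DG KO a, 21 without DG control a and 0 without DG KO b, DG KO c, SVZ control c, SVZ KO b or SVZ KO c in turn. It was 1 and 2 without SVZ control a and b.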

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

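The tests of list differences between tissues, of the place of the SVZ libraries and of the precursor list against the myelin list were chosen only after the results were seen. The groups of 3 libraries are too small for a test of outlying samples. The KO effect differed between the tissues, by the test of the difference itself, for 5 genes. Among them, the SVZ effect minus the DG effect on the log2 scale was 1.01 for Eno2, 3.24 for n-R5s141, 1.11 for Dagla and -0.85 for Abca9. In 6 of 100 splits of both tissues' libraries, the real one included, at least 5 genes passed, so a random grouping of the libraries is not excluded as the source of this count. The highest of the other splits gave 891 genes. That split kept the DG groups and set SVZ KO b, KO c and control a against the other SVZ libraries, with KO b and KO c on the side of the DG controls. In it, a KO effect of the same sign in both tissues adds up in the difference instead of cancelling. Its count is therefore not that of a grouping free of the KO effect. With the same SVZ libraries on opposite sides the count was 0, so it depended on which side KO b and KO c took relative to the DG groups. Another split, with the real SVZ groups and DG control b, KO b and KO c against the other DG libraries, gave 112 genes, which points to a structure of the DG libraries that does not follow genotype. These 3 had the highest DG scores of the striatal list (5.54, 4.55 and 5.24, against 3.31 to 3.59).

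By camera with the preset correlation, the effects of 15 lists differed between tissues. Relative to the DG, the median SVZ effect was higher by 0.69 for mature neurons and synapses, 0.44 for dentate granule neurons, 0.50 for CA pyramidal neurons and 0.35 for immediate early genes. The difference was -0.57 for ribosomal proteins, -0.66 for microglia and macrophages, -1.30 for meningeal and vascular fibroblasts and -0.505 for neural stem cells and radial glia. It was -0.43 for endothelial cells and pericytes, -0.30 for cholesterol biosynthesis, -0.89 for ependymal cells and motile cilia, -0.25 for Notch signalling, -0.42 for the cell cycle list, -0.42 for neuroblasts and -1.30 for blood. None of these passed with an estimated correlation, where the lowest adjusted p was 0.086. Without the library labelled KO a, 15 lists were called again, 13 of them the same. The immediate early genes (-0.06, adjusted p = 0.90) changed sign and lost their call, the cell cycle list lost its call (-0.29, adjusted p = 0.091), and the lists of myelin (-1.74, adjusted p = 4.24e-05) and astrocyte genes (-0.43, adjusted p = 0.012) gained one. With an estimated correlation none passed in this setting either (lowest adjusted p = 0.22, and 0.59 for the myelin and astrocyte lists).

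The SVZ library labelled KO a lay with the controls in Dpy30, in the genes called in the DG and in the myelin list. The mean log2 value of that list was 5.61 in KO a, 5.25 to 6.26 in the SVZ controls and 3.07 and 2.75 in KO b and KO c. On a scale from 0 (mean of the SVZ controls) to 1 (mean of KO b and KO c), KO a lay at -0.19. The 3 controls lay from -0.09 to 0.08 (SD 0.087). The scale was made from 104 genes called in the DG without use of the SVZ libraries. Whether both tissues came from the same mice is not given in the sources used here. By Kdm5d, DG KO a was female (0.0037 FPKM) and SVZ KO a, b and c were male (1.39, 1.38 and 1.13 FPKM). The KO libraries as labelled thus did not all come from the same mice in both tissues. Where mice were shared, the DG calls may share effects of the animals with the SVZ libraries. The place of KO a on this scale, with its Dpy30 value of 8.83 FPKM, fits tissue without the deletion, by a wrong label or a deletion that did not happen. It argues against a swap with an SVZ control, of which the highest lay at 0.081. If the KO genotype (Dpy30F/-) lacks an allele in all cells, KO tissue without the deletion would hold a single intact allele. Dpy30 might then lie at or below the controls (7.73, 8.25 and 9.43 FPKM), which a single value of 8.83 FPKM cannot settle. Against a plain control sample stand Man1a2, in which KO a lay with KO b and KO c at 8.58 FPKM, and Dagla and Abca9, at 22.0 and 0.858 FPKM (controls 15.0 to 17.5 and 1.42 to 1.60 FPKM). These genes were picked for separating the groups or tissues. KO a also lay with KO b and KO c in the 5S copies n-R5s141, n-R5s149 and n-R5s111, at 8.33, 11.3 and 6.46 FPKM. These copies are near-identical and so no separate evidence. In the DG, n-R5s141 was at 6.39, 4.81 and 10.5 FPKM in the controls and 8.64, 5.64 and 3.51 FPKM in the KO libraries. It did not follow genotype there, so the 5S values cannot place KO a. Over all tested genes, the SD of the log2 difference was 0.3383, 0.2502 and 0.2455 between KO a and SVZ control a, b and c. Between KO a and KO b and KO c it was 0.4051 and 0.392, and among the controls 0.2775 to 0.3421. Over all genes KO a thus lay with the controls, which does not tell a wrong label from a deletion that did not happen. Lists fixed beforehand went both ways. In the microglial and astrocyte lists, KO a (mean log2 3.225 and 5.441) lay below every SVZ control, toward KO b and KO c. Without KO a the microglial median went from -0.46 to -0.50 and the astrocyte median from -0.51 to -0.55. In the immediate early and cell cycle lists, KO a (3.867 and 1.134) lay beyond the controls, away from KO b and KO c. With the library labelled KO a among the KO, the SVZ groups did not overlap for 15.6% of the tested genes, where exchangeable libraries give 10%. Since KO b and KO c differed from the controls, a control labelled KO could also raise this share, so it cannot place KO a. Whether the label or the deletion is at fault stays open.

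The myelin list had a negative median in both tissues, though with all libraries 0 of 19 members passed in the DG and 0 of 20 in the SVZ, and neither list was called with an estimated correlation (adjusted p = 0.79 and 0.50). In the DG the striatal list itself had a median of 0.39, and with its score as a term the myelin median was -1.54 (SE over libraries 0.53) against -1.35 without the term. Without DG control b it was -0.78 both with and without the term. This argues against less striatal tissue in the KO dissections as the whole cause, though the value passed the bound of -1 by little more than its SE and only with DG control b. In the SVZ without the library labelled KO a, the precursor list's median lay 2.59 (SE over libraries 0.46, and 2.36 to 2.88 with each other library left out in turn) above that of the myelin list, which argues against loss of the whole lineage. A candidate explanation that stays open is fewer mature oligodendrocytes or less myelin gene expression in each, which these bulk values do not separate, and another is a share of white matter that differed with dissection.

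The ribosomal protein list had a positive median in the DG KO, with 2 of 23 members past the threshold and no call with an estimated correlation (adjusted p = 0.79). Its median stood 0.41 (SE over libraries 0.13) above that of genes matched on transcript length and GC content, whose own median was 0.19, so such a bias may account for part, and the spread leaves open how much. After median centring the median was 0.53 (SE over libraries 0.14, and 0.42 to 0.67 with each library left out in turn), which argues against the authors' scaling. Read depth was higher in all DG KO libraries, and the slope of the ribosomal score on log2 depth within the groups gave -0.0225 (SE 0.21) over the gap between them, too imprecise to decide, so depth and genotype cannot be told apart for these genes.

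The 6 libraries of a tissue can be split in 10 ways, the real one included, too few for a share under 0.05. In the DG the real split gave 108 genes and the highest other 10 (1 of 10 splits gave as many). For lists these were 10 and 18, with 6 of 10 splits giving as many. In the SVZ the real split gave 1 gene and the highest other 1 (2 of 10), and 11 and 13 lists (5 of 10). Splits that mix the genotypes thus gave as many lists as the real split in both tissues. The number of lists called with the preset correlation is therefore no evidence of a genotype effect. For genes passing in both tissues the real count was 0, which any split reaches (100 of 100, the highest other 1), so this comparison says nothing about chance.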

How the results depend on the processing

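The sex term, the striatal term and the list differences between tissues were chosen only after the data were seen. No paired analysis was possible because the table columns carry no replicate number. Count models were not run, since the tables hold FPKM and no reads. Leaving out each library gave 0 to 3 DG genes (main 108), 0 to 1317 SVZ genes (1), 0 to 33 genes in both tissues (0), 0 to 258 genes differing between tissues (5), 8 to 13 DG lists (10) and 9 to 14 SVZ lists (11). The Dpy30 log2 fold change ran from -0.52 to -0.38 in the DG and from -0.67 to -0.29 in the SVZ, passing only without the library labelled KO a (adjusted p 0.023, and 0.023 to 0.96 over all SVZ alternatives). With a minimum of 2 FPKM, a setting in which fewer genes were tested, 241 DG genes and 13 differences passed. With a pseudocount of 0.1, 2 differences passed. With the sex term these were 3 DG genes, 0 SVZ genes and 14 differences, and with the striatal term 424 DG genes. Tested by themselves, 1 DG transcript passed. An unadjusted p under 0.05 with a fold of at least 2 gave 447 DG and 343 SVZ genes, and the authors' deposited table at an FDR under 0.05 gave 13 DG transcripts. With an estimated correlation 0 DG and 0 SVZ lists were called. The cause of these changes was not tested. The DG log2 fold change of n-R5s141, -0.26 with all libraries, ran from -0.53 to 0.02 over leaving out each library and changed sign to 0.01 without DG control c and to 0.0188 without DG KO c. The difference between tissues of the immediate early genes changed sign from 0.35 to -0.0553 without SVZ KO a, the 1 setting run for list differences, in which 15 lists were called (main 15). No other called list difference, and no other called list or gene named in the report for a tissue, Xist and Kdm5d aside, changed sign in the settings run for that tissue. Of the DG genes named, 4 lost their call with a pseudocount of 0.1, 3 with no filter on low values and 5 with robust eBayes, and 0 gained one there. Of the called lists, oligodendrocyte precursors in the DG and Wnt signalling in the SVZ lost their call under quantile normalization, median centring and the minimum of 2 FPKM. Each of the 11 SVZ lists except precursors stayed called without the library labelled KO a. The depth of 26.7 to 66.0 reads per FPKM in 1 kb limits genes near 0.5 FPKM most.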

Other observations

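Lists that were not called in the DG included some with members that went together. Ependymal and motile cilia genes had positive log2 fold changes for 13 of 14 members with a median of 0.60 (camera adjusted p = 0.051), and Foxj1, the master regulator of motile cilia, was at 3.54 ± 0.966 FPKM in DG control and 9.34 ± 4.86 FPKM in DG KO (SD, n = 3). All 17 Notch signalling genes were positive, with a median of 0.23 (camera adjusted p = 0.083). None of the 19 SET1/MLL subunits, Dpy30 included, passed in either tissue with all libraries. The medians of that list were 0.09 in the DG and 0.14 in the SVZ (camera adjusted p = 0.86 and 0.13). Without the SVZ library labelled KO a, Dpy30 fell and 1 other subunit rose past the threshold. The SVZ list median was then 0.23, and the list was not called (camera adjusted p = 0.05002, and adjusted p = 0.65 with an estimated correlation). The reactive gliosis list had a median of 0.06 (camera adjusted p = 0.86) in the DG, with Vim at 16.4 ± 1.78 and 33.4 ± 9.50 FPKM in control and KO and Gfap at 69.8 ± 28.0 and 27.2 ± 2.90 FPKM.

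The remaining DG medians, each with its camera adjusted p in brackets, were 0.39 for GABAergic and striatal neurons (0.27), 0.04 for thalamic and habenular neurons (0.27), 0.15 for interferon response (0.31), 0.14 for microglia and macrophages (0.31), -0.04 for intermediate progenitors (0.46), 0.04 for cholesterol biosynthesis (0.86), 0.10 for p53 targets (0.86), 0.10 for endothelial cells and pericytes (0.86), 0.14 for Wnt signalling (0.86), -0.01 for choroid plexus (0.86), 0.12 for Hedgehog signalling (0.86), 0.02 for oxidative phosphorylation (0.86), -0.06 for heat shock and stress (0.10) and 0.24 for neuroblasts (0.94). None of these lists was called. The camera direction was opposite to the median for the striatal, thalamic, Wnt, gliosis and oxidative phosphorylation lists. In the SVZ the lists not called had medians of -0.09 for ependymal cells (0.094), -0.10 for Hedgehog signalling (0.11), -0.08 for Notch signalling (0.18), -0.02 for ribosomal proteins (0.21), -0.12 for thalamic and habenular neurons (0.34), 0.10 for mature neurons (0.38), 0.10 for interferon response (0.38), -0.01 for gliosis (0.44), 0.06 for the cell cycle (0.44), -0.18 for blood (0.58), 0.01 for p53 targets (0.60), -0.13 for immediate early genes (0.61), -0.08 for intermediate progenitors (0.82), -0.18 for choroid plexus (0.82), 0.00029 for oxidative phosphorylation (0.84), 0.0049 for heat shock (0.93), 0.04 for granule neurons (0.97) and -0.03 for CA pyramidal neurons (0.998). The camera direction was opposite to the median for the CA pyramidal and oxidative phosphorylation lists. The 2 measured HOX list genes had medians of 0.18 in the DG and -0.11 in the SVZ and were not tested as a set.

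The DG libraries differed among themselves in region markers. The granule neuron gene Prox1, chosen after its values were seen, was at 2.30, 0.963 and 10.7 FPKM in DG control a, b and c and between 1.19 and 1.93 FPKM in the DG KO libraries. The mean log2 value of the choroid plexus list was 3.77, 2.76 and 2.14 in the controls and 2.28, 4.66 and 2.26 in the KO libraries. That of the granule neuron list was 2.27 to 2.985 in the DG and 2.64 to 2.80 in the SVZ libraries. For the striatal list these ranges were 3.31 to 5.54 and 4.84 to 5.36. The tissues were normalized separately and the measured members can differ, so these levels are a rough guide. By them the DG libraries showed little enrichment of granule neuron markers, and how much dentate tissue each held was not tested.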
